A study of Mus musculus with 6 samples.

How the data were processed

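RNA of the hippocampus of 6 mice, 3 wildtype and 3 transgenic, all 63 weeks old, was labelled with biotin and hybridised to Affymetrix arrays, 1 array per animal, per the labels' protocols. The replicates were separate animals per the labels, which give neither sex nor batch. The deposited values are log2 expression per probe, made by the authors with RMA, per the submitters' processing notes, which name the build mm8. RMA corrects the background, normalizes between arrays and summarises the probes of a transcript. Its version and any filter are not given in the sources used here. The array medians lay between 7.44 and 7.47 but the quartiles differed between arrays. Differences of dim probes are generally compressed in such values. Values per single probe and scanner intensities were not analysed here.

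Of the 23332 probes in the table, GEO's platform annotation, which can be old, gave 1 gene symbol for 14996 and several for 1019, while 7317 are unnamed here. The 14996 probes, of 14860 genes, were tested, and symbols were looked up by gene identifier in a RefSeq table of GRCm38.p6, which held 14941 of them and changed 0 names. That table served only for names and for which genes neighbour each other, since the builds differ. For 135 genes with more than 1 probe, the probe with the highest mean over the 6 arrays stood for the gene in gene lists, named genes and gene order. The probes outside the test were fitted separately, and in limma with Benjamini-Hochberg adjustment 0 of the 1019 with several symbols and 0 of the 7317 unnamed ones passed, with lowest adjusted p of 0.349 and 0.265, while 44 and 584 had an unadjusted p under 0.05.

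The transgenic and wildtype groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes on the deposited values, no covariate) with Benjamini-Hochberg adjustment over the 14996 probes. The thresholds of a false discovery rate of 10% and 2-fold are those of the series, which names no test. The rate was also counted alone, and the probes whose 95% interval excluded a 2-fold difference were counted. The tests are two-sided. An exact permutation test of 3 against 3 cannot give a p below 0.1. Errors of differences are limma's moderated standard errors. The median residual SD was 0.098 on the log2 scale.

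Before the data were examined, 39 gene lists were fixed for cell types, pathways and neighbouring tissue, along with the rule for named genes. The rule took every gene past both thresholds, the 10 genes with the smallest p in each direction whose groups did not overlap and the 5 with the largest difference in each direction. It also took 5 genes of the lamina and of astrocytes, of which Lmna, Lmnb2, Zmpste24 and Gfap had a probe with 1 symbol, and up to 4 members with the smallest p per list. A few further genes were named after their values were seen, as parts of the run on chromosome 3. Lists with at least 5 measured genes were tested with camera in limma at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 37 lists and a threshold of 0.05. Camera with an estimated correlation and fry were alternatives. Among the 15 lists that passed, a pair shared at most 1 measured gene. Within lists, a gene was counted as past adjusted over the list alone at a rate of 10%.

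After the 7 called genes were seen to be neighbours, 14802 genes were put in chromosome order and runs of 3 to 40 genes were scanned for the most extreme mean shift, with 1000 shuffles of gene order, and 1000 shuffles among genes of like mean level, for comparison. The methods were tested on simulated data of 14996 probes with the real means and spreads for the comparison of transgenic with wildtype. Of 200 changed probes over 10 runs, 89.4% were recovered at 1.5-fold, 99.1% at 2-fold and 99.5% at 4-fold, with 10.7% of calls false. A list shifted by 0.3 was recovered in 10 of 10 runs, with 4 calls on other lists in all. A run of 20 neighbours lowered by 0.5 was recovered in 10 of 10. The simulated noise was independent between probes and held no differences among animals of a group, unlike the real data. These shares therefore check the methods and do not give the power or the rate of false calls in the real data.

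Alternatives were the replicate number as a block, a further quantile normalization, centring on array medians, leaving out the dimmest 33.3% of the probes, eBayes with trend and robust estimation, no variance moderation, array weights, all probes, the mean of a gene's probes, thresholds of 5%, an unadjusted p of 0.05 and 1.5-fold, and leaving out each array in turn. Chosen after seeing the data were the mean signal of the Y-linked probes of Eif2s3y and Kdm5d as a covariate, leaving out wildtype replicates 2 and 3, cyclic loess, and leaving out the run on chromosome 3.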

Results

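Expression was measured in the hippocampus of 6 mice aged 63 weeks, 3 wildtype animals and 3 transgenic animals that the labels call HGPS. HGPS is the usual abbreviation of Hutchinson-Gilford progeria syndrome, a premature ageing disorder caused by mutations of the lamin A gene, LMNA. One Affymetrix array was hybridised per animal, so the number of arrays limits the precision. The deposited table held 23332 probes on a log2 scale, with array medians between 7.44 and 7.47. Arrays of the same group correlated with each other at a mean r of 0.991 to 0.994 across probes, arrays of different groups at 0.988 to 0.994, and no array was a copy of another. Wildtype replicate 1 had a mean r of 0.994 with the transgenic arrays and of 0.992 with its own group, and its r of 0.996 with transgenic replicate 1 was the highest of the 15 pairs. Of the probes, 14996 carried 1 gene symbol and were tested. The comparison addressed which genes and gene groups differed between transgenic and wildtype hippocampus at this age. Genes of the Y chromosome were at a high level in wildtype replicates 2 and 3 alone, so the groups also differed in that signal.

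In transgenic hippocampus 7 genes fell and none rose at a false discovery rate of 10%, and all 7 lay close together on chromosome 3. Nlgn1, which encodes a postsynaptic adhesion protein of excitatory synapses, fell by 0.94 ± 0.07 on the log2 scale (SE, n = 3 per group), to 52.0% of its wildtype level. Hltf, a DNA helicase of the response to stalled replication, fell by 0.97 ± 0.08, and the uncharacterised gene 4632415L05Rik fell by 0.94 ± 0.10. Gyg, the primer of glycogen synthesis, fell by 0.78 ± 0.07, and the cAMP phosphodiesterase Pde7a fell by 0.74 ± 0.07. Hps3, which acts in the formation of lysosome-related organelles, fell by 0.70 ± 0.06, and the transcriptional corepressor subunit Tbl1xr1 fell by 0.69 ± 0.06. The limma adjusted p was 0.0226 for Nlgn1, 0.0799 for 4632415L05Rik and 0.0239 for each of the other 5 genes. In each of these genes all 3 transgenic animals lay below all 3 wildtype animals, for which the two-sided exact permutation p is 0.1, the smallest that 3 against 3 can give.

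None of the 14996 probes passed both a false discovery rate of 10% and a 2-fold difference, the thresholds stated for the series, in limma, while 1592 had an unadjusted p under 0.05, of which 872 were higher and 720 lower. The count of 7 fell to 0 when wildtype replicate 2, wildtype replicate 3, transgenic replicate 1 or transgenic replicate 2 was left out, without variance moderation, with the signal of Y-linked genes as a covariate, without both wildtype arrays that carried this signal, and when all 23332 probes were tested together, where the lowest adjusted p was 0.111. The count was also 0 with the replicate number as a block. Over all settings the log2 difference stayed between -0.99 and -0.85 for Nlgn1 and between -0.74 and -0.69 for Hps3. Without wildtype replicate 1 the count was 103, including all 7 genes, with 19 lower and the others higher, and 27 probes then passed both thresholds. That fit compares only the wildtype arrays that carried the Y-linked signal with transgenic arrays that did not. Genotype therefore cannot be told apart there from whatever else sets those wildtype animals apart.

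**Figure D1:**
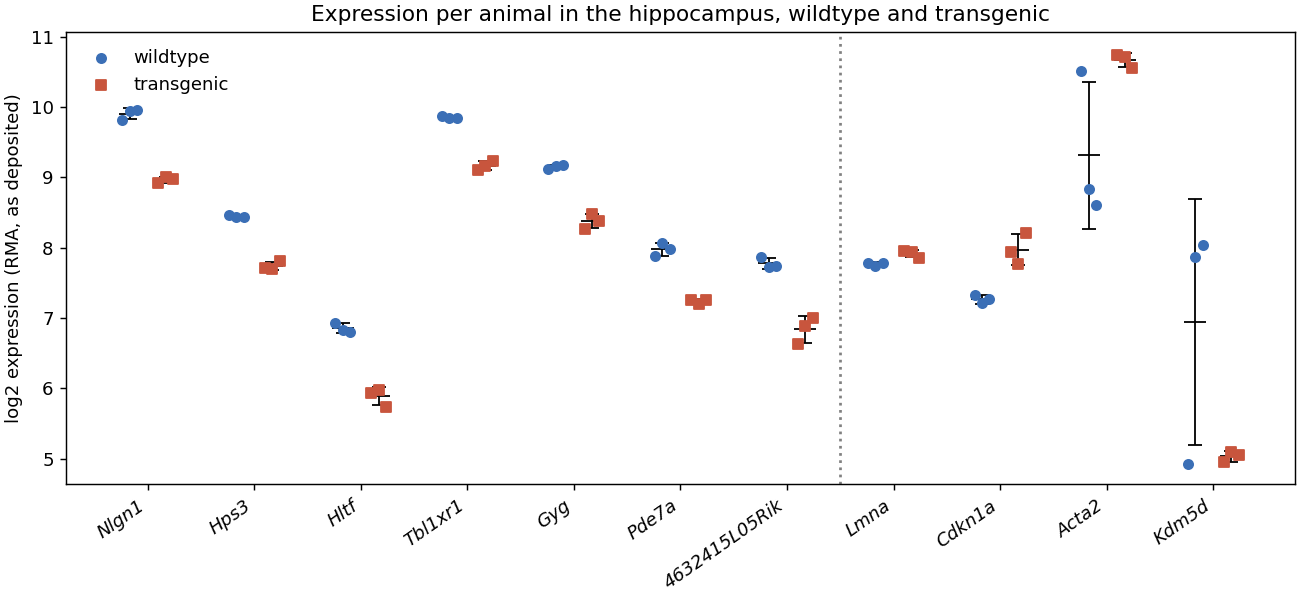
Log2 expression of the 7 genes past a false discovery rate of 10% (left of the dotted line) and of Lmna, Cdkn1a, Acta2 and Kdm5d (right) in each of 3 wildtype and 3 transgenic animals, with the mean and SD of each group in black. In the 7 genes the groups are apart, while in Acta2 and Kdm5d wildtype replicate 1 lies with the transgenic animals.

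The 7 genes belonged to a run of 20 measured neighbours on chromosome 3, in the gene order of the GRCm38.p6 assembly. From one end the run held Mtfr1, Pde7a, Dnajc5b, Crh, 4632415L05Rik, Hps3, Hltf, Gyg, Cpa3, Cpb1, Agtr1b, Tbl1xr1, Nlgn1, Spata16, Ect2, Nceh1, Tnfsf10, Ghsr, Fndc3b and Pld1. All 20 were lower in the transgenic group, with a median log2 difference of -0.44 (interquartile range -0.71 to -0.32), and 14 had an unadjusted p under 0.05. Nceh1, which hydrolyses cholesterol esters, had a log2 difference of -0.71 ± 0.09 (SE) without passing the threshold (limma adjusted p = 0.135). Crh, the gene of corticotropin-releasing hormone, had a difference of -0.39 ± 0.10 (limma adjusted p = 0.431), and the difference of the ghrelin receptor gene Ghsr was -0.06 ± 0.08. The 6 run members at or above the median probe level had a median of -0.71, or 61.3% of wildtype, and the 14 dimmer members a median of -0.34. The 20 genes flanking the run, 10 on each side, had a median of -0.06, and 12 of them were below 0. With the signal of Y-linked genes as a covariate the median of the run was -0.61, and without both wildtype arrays that carried this signal it was -0.62. In 1000 shuffles of gene order no run was as extreme. The run was singled out after the values had been seen.

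**Figure D2:**
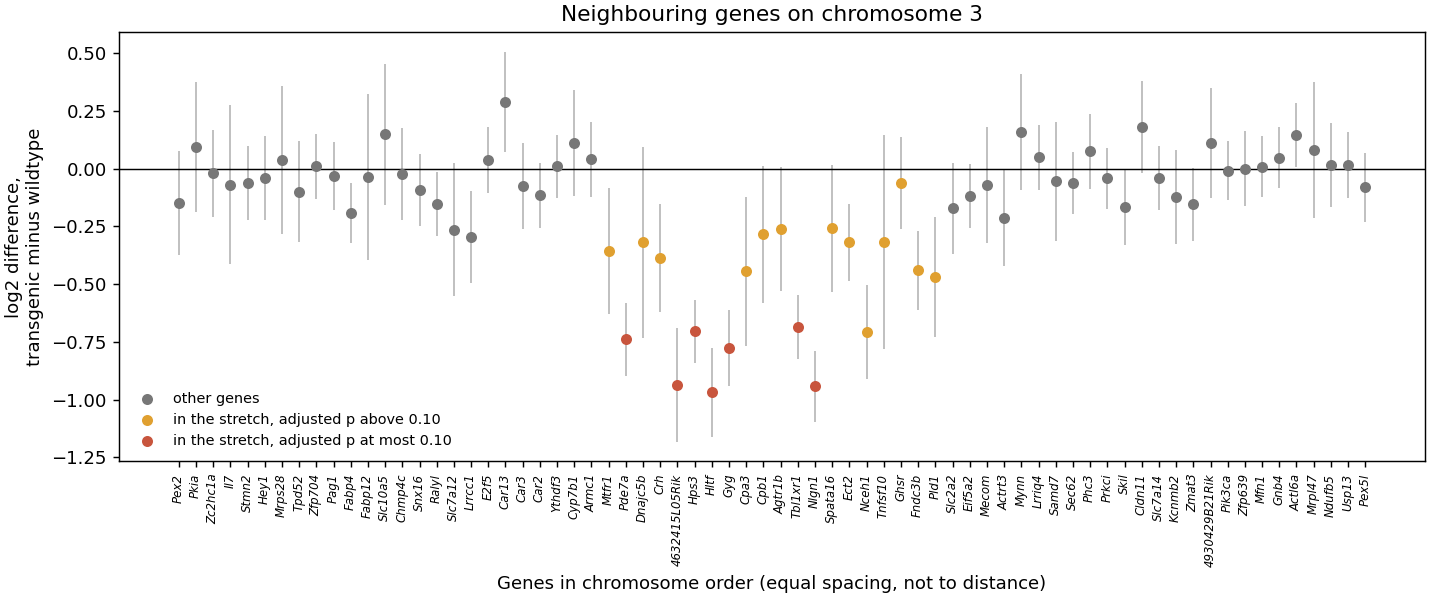
Log2 difference (transgenic minus wildtype, n = 3 per group) with its 95% confidence interval for the run of 20 genes on chromosome 3 and 25 measured neighbours on each side, in chromosome order and not to distance. All 20 genes of the run lie below 0, with a median of -0.44.

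The genes most directly tied to the disorder differed little. Lmna, which encodes lamins A and C, was measured at 7.77 ± 0.02 in wildtype and 7.92 ± 0.05 in transgenic hippocampus (mean ± SD, n = 3). Its log2 difference of 0.15 (95% interval 0.01 to 0.28) did not pass the threshold (limma adjusted p = 0.451), and whether the mouse probe detects transcripts of the transgene is not given in the sources used here. Zmpste24, the protease that processes prelamin A, differed by 0.17 ± 0.07 (SE, limma adjusted p = 0.469). The B-type lamin gene Lmnb2 differed by 0.06 ± 0.06 (limma adjusted p = 0.723). The 18 measured genes of the nuclear lamina and LINC complex (the bridge from nucleus to cytoskeleton) rose as a list in camera, 14 of them above 0, with a median of 0.08 (adjusted p = 0.014, adjusted p = 0.527 with an estimated correlation). Tmem43, an inner nuclear membrane protein, had the smallest p of these with a difference of 0.25 ± 0.07. No member passed over all genes or adjusted over the list alone, and with the signal of Y-linked genes as a covariate the list had a median of 0.01 and did not pass (adjusted p = 0.871). Its mean level relative to the 6 arrays was 0.02 in wildtype replicate 1, -0.09 and -0.05 in wildtype replicates 2 and 3 and 0.02 to 0.05 in the transgenic animals. The list also did not pass without wildtype replicate 2 (adjusted p = 0.149), with a further quantile normalization (adjusted p = 0.0665) or without the dimmest 33.3% of probes (adjusted p = 0.0725).

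Of 39 gene lists, 37 had at least 5 measured genes, and 15 of these differed in camera at an adjusted p of 0.05, 14 higher and 1 lower in transgenic hippocampus. Camera compares a list with all other genes under a preset correlation of 0.01 between its genes. With a correlation estimated from the arrays 0 of the 37 lists passed, 3 having an unadjusted p under 0.05, and the lowest adjusted p was 0.312, so each call below rests on the preset value. Fry, which tests whether a list's genes move on balance one way without comparing them with other genes, called 2 lists. These were the glucocorticoid response (higher, adjusted p = 0.0179) and DNA damage repair (lower, adjusted p = 0.0455).

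Genes of the meninges and of the endothelium had the smallest p values of all lists at the preset correlation, while with an estimated correlation the glucocorticoid response had the smallest. All 17 measured genes of meninges and fibroblasts were higher in the transgenic group, with a median log2 difference of 0.59 (camera adjusted p = 1.74e-09, adjusted p = 0.439 with an estimated correlation). Among them Ptgds, the prostaglandin D synthase of the arachnoid, had a difference of 1.19 ± 0.36 (SE), the organic anion transporter gene Slc22a6 one of 0.97 ± 0.30 and the matrix gene Fbln1 one of 0.52 ± 0.16. None passed over all genes and 15 passed adjusted over the list alone. All 19 endothelial genes were higher, with a median of 0.22 (camera adjusted p = 1.74e-09, adjusted p = 0.439 with an estimated correlation). They included the tight junction gene Cldn5 at 0.37 ± 0.10, the junctional cadherin gene Cdh5 at 0.34 ± 0.10 and Esam at 0.27 ± 0.06. None passed over all genes and 13 passed adjusted over the list alone.

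Of 14 genes of pericytes and smooth muscle, 11 were higher, with a median of 0.27 (camera adjusted p = 0.002, adjusted p = 0.527 with an estimated correlation). The intermediate filament gene Des differed by 0.53 ± 0.09 (SE), the plasma and pericyte protein gene Vtn by 0.64 ± 0.18 and the pericyte gene Higd1b by -0.32 ± 0.10. None passed over all genes, and 5 higher and 1 lower passed adjusted over the list alone. All 13 genes of choroid plexus and ependyma were higher, with a median of 0.58 (camera adjusted p = 0.00181, adjusted p = 0.527 with an estimated correlation), but 1 had an unadjusted p under 0.05 and none passed over all genes or adjusted over the list alone. The sulfate transporter gene Slc13a4, the 1 with such a p, differed by 1.29 ± 0.45 and the choroid transcription factor gene Otx2 by 0.71 ± 0.45. The 2 genes varied differently among the transgenic animals. Slc13a4 had 9.60 in transgenic replicate 2 and 9.68 and 9.44 in replicates 1 and 3, while Otx2 had 6.95 against 8.03 and 8.28. The pericyte list did not pass without transgenic replicate 1 (adjusted p = 0.0535), nor the choroid list without wildtype replicate 3 or transgenic replicate 1 (adjusted p = 0.12 and 0.0648) or with array weights (adjusted p = 0.0603).

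These 4 lists moved with a difference among the wildtype animals. The Y-linked genes Eif2s3y and Kdm5d had a mean log2 level of 8.41 and 8.45 in wildtype replicates 2 and 3, against 4.63 in wildtype replicate 1 and 4.67, 4.78 and 4.70 in the transgenic animals. The labels give no sex. Expression of these genes of the Y chromosome marks wildtype replicates 2 and 3 as male, while wildtype replicate 1 and the transgenic animals showed no such signal. The groups were therefore unbalanced by sex as read from this signal, and the main comparison is not one of genotype alone. The mean level of the meningeal list, relative to the mean of the 6 arrays, was -0.57 and -0.61 in wildtype replicates 2 and 3, 0.22 in wildtype replicate 1 and 0.25 to 0.36 in the transgenic animals. With the Y-linked signal as a covariate, the median difference was 0.15 for the meningeal list (camera adjusted p = 0.0184) and 0.12 for the endothelial list (adjusted p = 0.00282). The pericyte list then had a median of 0.02 and no longer passed (adjusted p = 0.386), and the choroid list turned to a median of -0.19 without passing (adjusted p = 0.181). Leaving out wildtype replicates 2 and 3 left 1 wildtype array, so only median differences are given for that fit. The median was then 0.33 for immediate early genes, 0.12 for reactive astrocytes and 0.11 for endothelial cells. For the circadian clock it was 0.11 and for the glucocorticoid response 0.10. The meningeal list had 0.13, the nuclear lamina list 0.01 and the choroid list -0.21. Like the fit with the covariate, this comparison rests on wildtype replicate 1, the only wildtype array without the Y-linked signal. Neither is therefore a separate check of the other, and any peculiarity of that animal would appear as a group difference.

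**Figure D3:**
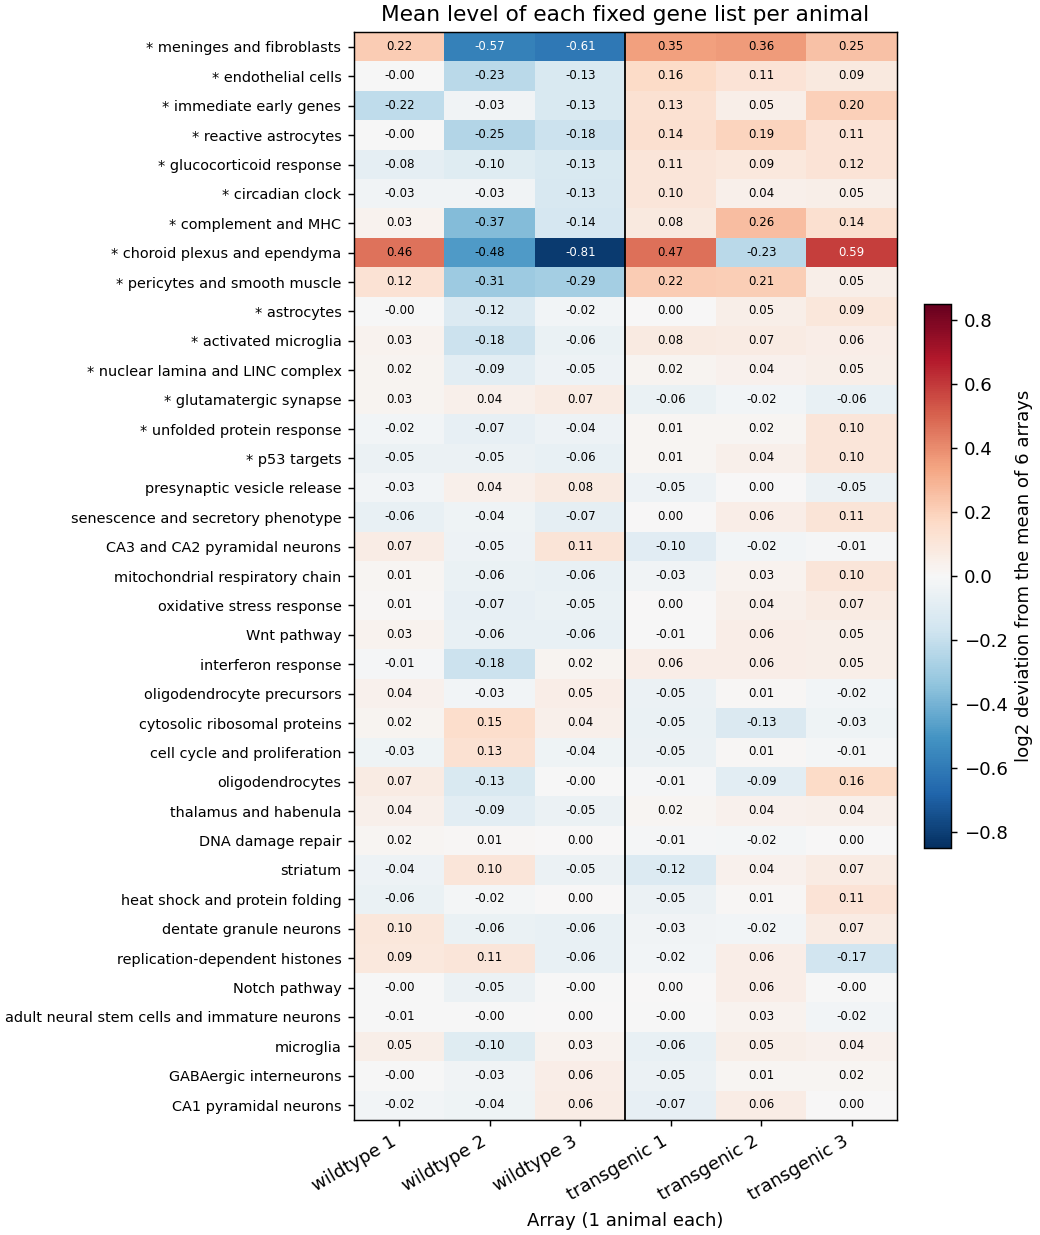
Mean log2 deviation of each tested gene list from the mean of the 6 arrays, per animal, in order of the camera p, with an asterisk on the 15 lists at an adjusted p of at most 0.05. Meningeal genes are at -0.57 and -0.61 in wildtype replicates 2 and 3 and at 0.22 to 0.36 in the other 4 animals.

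Genes induced by neuronal activity were higher in the transgenic group. All 20 immediate early genes lay above 0, with a median log2 difference of 0.27 (camera adjusted p = 1.32e-08, adjusted p = 0.439 with an estimated correlation). The activity-dependent transcription factor genes Npas4 and Egr1 differed by 0.64 ± 0.15 and 0.31 ± 0.06 (SE), and Klf4 and Fosl2 by 0.34 ± 0.08 and 0.28 ± 0.07. None passed over all genes and 11 passed adjusted over the list alone. With the Y-linked signal as a covariate the median was 0.33 (camera adjusted p = 2.93e-13). That fit rests on wildtype replicate 1, the only wildtype array without this signal and the lowest array for the list. Relative to the mean of the arrays, the list was at -0.22 in this animal and at -0.03 and -0.13 in wildtype replicates 2 and 3. The transgenic animals lay at 0.05 to 0.20. The higher median with the covariate therefore reflects a single wildtype animal.

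Of 16 genes of the glucocorticoid response 13 were higher, with a median of 0.17 (camera adjusted p = 4.82e-05, adjusted p = 0.312 with an estimated correlation). None passed over all genes and 7 passed adjusted over the list alone. Cdkn1a, the gene of the cell cycle inhibitor p21, differed by 0.70 ± 0.11 (SE, limma adjusted p = 0.324), the iron-binding acute phase gene Lcn2 by 0.59 ± 0.15 and the phosphatase gene Dusp1 by 0.51 ± 0.14. Each of these is also on another called list, Cdkn1a among p53 targets, Lcn2 among reactive astrocyte genes and Dusp1 among immediate early genes. The 10 glucocorticoid genes on no other list had a median of 0.11. Of 15 genes of the circadian clock 10 were higher, with a median of 0.13 (camera adjusted p = 0.00142, adjusted p = 0.439 with an estimated correlation). None passed over all genes and 6 passed adjusted over the list alone. Per1, a gene of both lists, differed by 0.24 ± 0.06, the clock repressor genes Bhlhe40 and Bhlhe41 by 0.30 ± 0.08 each, and Hlf by 0.27 ± 0.08. Both lists passed with the Y-linked signal as a covariate, each at a median of 0.10 (camera adjusted p = 0.00282 and 0.0184). That fit rests on wildtype replicate 1 as the only wildtype array without this signal.

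Among glial and immune lists, 4 were higher in the transgenic group. Of 15 reactive astrocyte genes 13 were higher, with a median of 0.27 (camera adjusted p = 2.24e-05, adjusted p = 0.439 with an estimated correlation), and 9 passed adjusted over the list alone, none over all genes. The intermediate filament gene Vim differed by 0.69 ± 0.16 (SE), Emp1 by 0.51 ± 0.13 and the chemokine gene Cxcl10 by 0.34 ± 0.09, while the astrocyte filament gene Gfap differed by 0.26 ± 0.11 (limma adjusted p = 0.476). In Vim wildtype replicate 1 had 10.08, against 9.55 and 9.51 in wildtype replicates 2 and 3, and in Emp1 7.54 against 7.14 and 7.18. In Cxcl10 it was instead the lowest array. The groups overlapped in Gfap, with wildtype replicate 1 at 10.25 and transgenic replicate 1 at 10.16. With the Y-linked signal as a covariate the list's median was 0.12 and it passed (adjusted p = 0.00909), in a fit that rests on wildtype replicate 1. Of 19 general astrocyte genes 13 were higher, with a median of 0.09 (camera adjusted p = 0.0103, adjusted p = 0.527 with an estimated correlation), among them Ntsr2 at 0.23 ± 0.07, and none passed over all genes or adjusted over the list alone. Without wildtype replicate 2 this list did not pass (adjusted p = 0.149).

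Of 16 activated microglia genes 13 were higher, with a median of 0.11 (camera adjusted p = 0.0111, adjusted p = 0.527 with an estimated correlation), and 1 passed adjusted over the list alone, none over all genes. That gene was Cd74, the MHC class II chaperone, at 0.89 ± 0.22 (SE). Of 10 complement and MHC genes 9 were higher, with a median of 0.18 (camera adjusted p = 0.00181, adjusted p = 0.527 with an estimated correlation), including the class II gene H2-Aa at 0.66 ± 0.19 and the complement inhibitor gene Serping1 at 0.78 ± 0.26. Adjusted over the list alone 4 passed, and over all genes none. With the Y-linked signal as a covariate the astrocyte, activated microglia and complement lists no longer passed, at medians of 0.05, 0.03 and 0.11 (adjusted p = 0.281, 0.69 and 0.181). Wildtype replicate 1 had the highest wildtype level of all 4 lists. Relative to the mean of the 6 arrays, the reactive astrocyte list was at -0.0049 in this animal, -0.25 and -0.18 in wildtype replicates 2 and 3 and 0.11 to 0.19 in the transgenic animals. The complement list was at 0.03, at -0.37 and -0.14 and at 0.08 to 0.26 in the same order, and in Serping1 wildtype replicate 1 had 8.87, against 8.80 to 9.18 in the transgenic animals. The activated microglia list also did not pass without wildtype replicate 2 or transgenic replicate 1 (adjusted p = 0.122 and 0.0951). The 19 general microglia genes had a median of -0.01, a mean of 0.02 and a higher direction in camera, and did not pass (camera adjusted p = 0.879).

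Among neuronal lists the 16 genes of the glutamatergic synapse fell as a group, 11 of them below 0, with a median of -0.06 (camera adjusted p = 0.0211, adjusted p = 0.439 with an estimated correlation). Nlgn1 passed over all genes. Adjusted over the list alone 1 gene passed in each direction, Nlgn1 and the vesicular glutamate transporter gene Slc17a6, whose difference was 0.45 ± 0.12 (SE). The AMPA receptor subunit gene Gria3 differed by -0.17 ± 0.07 and the scaffold gene Dlg2 by -0.16 ± 0.07. The list no longer passed with the Y-linked signal as a covariate (median -0.05, adjusted p = 0.103), without the run on chromosome 3, which holds Nlgn1 (adjusted p = 0.126), without wildtype replicate 3 or without transgenic replicate 3 (adjusted p = 0.124 and 0.0704). Presynaptic vesicle release did not pass at a median of -0.06 over 17 genes (camera adjusted p = 0.0657), nor did CA3 and CA2 pyramidal neurons at -0.08 over 13 genes (adjusted p = 0.0711, adjusted p = 0.527 with an estimated correlation). The CA3 and CA2 list was called lower in 6 of 19 alternative settings. It was the 1 lower list called with the Y-linked signal as a covariate (median -0.05, adjusted p = 0.0248), a fit that rests on wildtype replicate 1. Another of the 6 left out wildtype replicates 2 and 3, which left 1 wildtype array, at a median of -0.05. The list also passed without wildtype replicate 2 alone (adjusted p = 0.00286), with cyclic loess (adjusted p = 0.0186), with a further quantile normalization (adjusted p = 0.0159) and with array weights (adjusted p = 0.0373). The presynaptic list (adjusted p = 0.607 with an estimated correlation) was called in 7 of the 19, among them without wildtype replicate 1 or transgenic replicate 2 (adjusted p = 0.0197 and 0.0398). In the CA3 and CA2 list Iyd differed by -0.42 ± 0.07 and the BCL2 family gene Bok by -0.40 ± 0.11, and 3 lower and 1 higher gene passed adjusted over the list alone, none over all genes. Dentate granule neurons, CA1 pyramidal neurons, GABAergic interneurons and adult neural stem cells with immature neurons did not pass, at camera adjusted p = 0.688, 0.919, 0.894 and 0.802. In the CA1 and GABAergic lists the medians were 0.02 and 0.03, while the means lay below 0 and camera's direction was lower.

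Damage and stress lists differed by little. Of 19 p53 target genes 12 were higher, with a median of 0.06 (camera adjusted p = 0.0426, adjusted p = 0.439 with an estimated correlation), and 4 passed adjusted over the list alone, none over all genes. They were Cdkn1a, Plk3 at 0.24 ± 0.07 (SE), the stress-induced gene Sesn1 at 0.27 ± 0.09 and Trp53inp1 at 0.20 ± 0.07. Of 19 genes of the unfolded protein response 12 were higher, with a median of 0.08 (camera adjusted p = 0.0348, adjusted p = 0.439 with an estimated correlation), including Xbp1, its transcription factor, at 0.31 ± 0.08, and none passed over all genes or adjusted over the list alone. With the Y-linked signal as a covariate neither list passed, at medians of 0.06 and 0.07 (adjusted p = 0.0608 and 0.197). The p53 list also did not pass without wildtype replicate 1 or 3 (adjusted p = 0.0763 and 0.0519) or transgenic replicate 2 or 3 (adjusted p = 0.0612 and 0.0727). With the replicate number as a block it did not pass either (camera adjusted p = 0.0546). Nor did the unfolded protein list pass without wildtype replicate 2 or transgenic replicate 3 (adjusted p = 0.122 and 0.072). The unfolded protein list passed in 9 of 19 alternative settings, and it did not pass with a further quantile normalization, with cyclic loess, with array weights or without the dimmest 33.3% of probes (adjusted p = 0.0941, 0.0905, 0.0719 and 0.0936). Senescence and its secretory phenotype did not pass (camera adjusted p = 0.0711), with 12 of 19 genes higher and 4 past the threshold adjusted over the list alone, among them Igfbp7 at 0.72 ± 0.20 and Ccl5 at 0.32 ± 0.08. In Igfbp7 wildtype replicate 1 had 10.07, against 9.30 and 9.37 in wildtype replicates 2 and 3 and 10.15 to 10.41 in the transgenic animals. Ccl5 did not follow this order, with 5.33, 5.15 and 5.34 in wildtype replicates 1 to 3. The senescence list was called higher in 5 of the 19 settings, among them without wildtype replicate 2 (adjusted p = 0.0371), and had adjusted p = 0.439 with an estimated correlation. DNA damage repair, with 16 of 23 genes lower and a median of -0.04, did not pass in camera (adjusted p = 0.392), nor did cell cycle and proliferation (adjusted p = 0.307), oxidative stress (adjusted p = 0.151) or heat shock and protein folding (adjusted p = 0.597).

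The remaining lists did not pass in camera in the main setting. Oligodendrocytes and their precursors had adjusted p = 0.327 and 0.24, the interferon response 0.175 and the mitochondrial respiratory chain 0.0774, with 17 of its 20 genes higher. For the Wnt and Notch pathways it was 0.167 and 0.802, for cytosolic ribosomal proteins 0.292 and for replication-dependent histones 0.802. Markers of the neighbouring thalamus and habenula and of the striatum had adjusted p = 0.361 and 0.392. Of these lists, oligodendrocytes passed without transgenic replicate 2 (adjusted p = 0.0261) and their precursors without wildtype replicate 2 (adjusted p = 0.0473). The respiratory chain passed without wildtype replicate 1 or transgenic replicate 1 (adjusted p = 0.0349 and 0.0488). The interferon response passed without wildtype replicate 3 (adjusted p = 0.0419), with a further quantile normalization (adjusted p = 0.0471) and with cyclic loess (adjusted p = 0.0481). Erythrocytes, with 4 measured genes, and sex-linked genes, with 2, were too small to test.

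The largest differences by fold did not pass the threshold. On average Eif2s3y was lower in the transgenic group by a log2 difference of -2.98 ± 1.14 (SE) and Kdm5d by -1.91 ± 0.76, both at a high level in wildtype replicates 2 and 3 alone. Of the 17 probes that differed at least 2-fold, 12 were higher. They were led by the retinoic acid synthesis gene Aldh1a2 at 1.39 ± 0.43, the smooth muscle actin gene Acta2 at 1.36 ± 0.45, Slc13a4, the matrix protein gene Itih2 at 1.21 ± 0.29 and Ptgds (limma adjusted p 0.431 to 0.433 for these 5). In Acta2 the 3 wildtype animals had 10.51, 8.83 and 8.60 and the transgenic animals 10.74, 10.71 and 10.55. The low mean of Supt4a in the transgenic group, with a difference of -1.28 ± 0.84, came from transgenic replicate 3 at 3.51, against 6.95 and 6.54 in the other transgenic animals. The olfactory receptor genes Olfr1167 and Olfr495 had differences of -1.15 ± 0.51 and -1.02 ± 0.33. In both, wildtype replicate 2 was the highest array. Olfr1167 had 7.07 there, against 5.09 and 5.68 in wildtype replicates 1 and 3, and Olfr495 had 7.66, against 6.39 and 6.67.

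Among genes whose groups did not overlap, the smallest p values in the higher direction belonged to Ccn2, a secreted matrix regulator, at 0.57 ± 0.08 (SE, limma adjusted p = 0.225), the endocytic kinase gene Aak1 at 0.44 ± 0.07 and Cdkn1a. They were followed by Tifa at 0.41 ± 0.07, Des, Ecm1 at 0.34 ± 0.06, the lactate dehydrogenase gene Ldhb at 0.65 ± 0.12, Hs3st3b1 at 0.35 ± 0.06, Mustn1 at 0.68 ± 0.12 and the cadherin gene Cdh1 at 0.46 ± 0.09. The limma adjusted p of the genes after Ccn2 was 0.315 to 0.4. In the lower direction the 7 called genes were followed by Nceh1, the vomeronasal receptor gene Vmn1r225 at -0.83 ± 0.11 (limma adjusted p = 0.146) and the nucleosome-binding protein gene Hmgn5 at -0.71 ± 0.09 (limma adjusted p = 0.148). The groups did not overlap in 2653 probes, or 17.7%, where chance gives 10% on average over groupings of the arrays. Probes vary together, so the share of any given grouping can lie well away from that average. The excess was not tested and is no evidence of genotype by itself.

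For most probes the interval excluded a large difference in the measured signal. The 95% interval of the log2 difference lay wholly inside a 2-fold change in either direction for 14742 probes, or 98.3%, and inside a 1.5-fold change for 13784, or 91.9%.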

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

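Alternatives chosen after the data were seen were the Y-linked signal as a covariate, leaving out both wildtype arrays with Y-linked signal (wildtype replicates 2 and 3), cyclic loess, and leaving out the run on chromosome 3. The other alternatives were planned. In limma the count of 7 probes past a false discovery rate of 10% was 12 with trend and robust estimation and 12 with array weights. It was 0 with the replicate number as a block, with no variance moderation, with the Y-linked signal as a covariate, without both Y-positive wildtype arrays, without the chromosome 3 run and with all probes tested, and 1592 probes had an unadjusted p under 0.05. Leaving out each array in turn gave 0 to 103, and the count past both the rate and 2-fold, 0 in the main setting, was 0 to 27, and 7 at 1.5-fold. The 7 genes kept their direction in every setting that measured them. The count of 15 lists was 7 with the Y-linked signal as a covariate (6 of the 15), 6 without both Y-positive wildtype arrays (5 of the 15), 0 with an estimated correlation, 2 with fry (1 of the 15) and 12 to 18 in the other settings. The list called newly was CA3 and CA2 pyramidal neurons in the first 2 of these and DNA damage repair with fry. Those first 2 fits both rest on wildtype replicate 1 as the only wildtype array without Y-linked signal, so they are not separate checks. The choroid plexus list turned lower, without passing, with the Y-linked signal as a covariate (adjusted p = 0.181) and without both Y-positive arrays (adjusted p = 0.142), where 1 wildtype array is assumed to vary like the others. The log2 difference of Lmna stayed between 0.12 and 0.18 and did not pass a false discovery rate of 10% in any setting, with an unadjusted p of 0.0389 in the main one. Among named genes 66 results over all settings lost their call and 42 gained one, and among lists 70 and 26. Leaving out the run on chromosome 3 removes the called genes by construction, no moderation leaves fewer degrees of freedom and all probes enlarge the adjustment, while for the other changes the cause was not tested. Whether the replicate numbers pair the arrays cannot be told. Deviations of same-numbered arrays correlated at 0.23, 0.149 and 0.023. Wildtype replicates 1 and 2 each correlated best with the same-numbered transgenic array, while wildtype replicate 3 correlated best with transgenic replicate 2. The block took the count of probes from 7 to 0 and that of lists from 15 to 14, without the p53 list (camera adjusted p = 0.0546). Dim probes limit what the arrays can show, and without the dimmest 33.3% of them 9 probes passed.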

Other observations

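The tests of the run on chromosome 3, of the meningeal genes and of the immediate early genes were chosen after their results were seen, while the splits of the arrays were planned for the counts of probes and lists.

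Choroid plexus genes, higher on average in the transgenic group, varied between the animals of each group. The mean level of the choroid and ependymal list, relative to the mean of the 6 arrays, was 0.46 in wildtype replicate 1, 0.47 and 0.59 in transgenic replicates 1 and 3, -0.23 in transgenic replicate 2 and -0.48 and -0.81 in wildtype replicates 2 and 3. Of the 9 other splits of the arrays, the one with the most calls set these 3 arrays with high choroid levels, wildtype replicate 1 and transgenic replicates 1 and 3, against the other 3 and called 32 probes at a false discovery rate of 10% in limma with Benjamini-Hochberg adjustment, 30 of them higher in the first set. Of these, 8 belonged to the 13 measured choroid genes, among them the folate receptor gene Folr1 at 1.42 and the transcription factor gene Otx2 at 1.34, and none to the run on chromosome 3. Since this split follows the choroid levels and was singled out as the highest, its choroid calls restate them and are no independent evidence. The split called more probes than the real one, 32 against 7, but it was picked for that count, and no conclusion is drawn from it. The 719 probes of olfactory receptor genes, most of them dim, had a median difference of -0.14, and their median level was 5.48 in wildtype replicate 2 and 4.98 to 5.06 in the other arrays. This array was higher over dim probes in general. The 1500 dimmest tested probes had a median of 5.03 there and 4.76 to 4.77 in the other arrays.

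The 10 splits of the 6 arrays into 3 and 3 are too few for a share under 0.05. The real split gave 7 probes past the rate and the highest other 32, so that 2 of the 10 splits gave as many. For both thresholds the real count was 0 and the highest other 13. That 10 of the 10 gave as many follows from the count of 0 and tests nothing. The real split had 14742 intervals inside 2-fold and the highest other 14789, with 9 of the 10 as high, and it had 15 lists and the highest other 15, with 2 of the 10 as many.

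On chromosome 3, 20 neighbouring genes were lower together in the transgenic group. In 1 of the 10 splits, the real one, the scan statistic was as large, at 2.32 against 1.75 in the highest other, and the splits are too few to exclude chance. Dim signal or normalization by level is argued against as the whole cause, since in 0 of 1000 shuffles of the differences among genes of like level was the most extreme run anywhere as extreme, the highest statistic being 1.66. A loss of 1 copy of the run in the transgenic animals may account for it, but not every gene showed such a drop. Of the 6 genes at or above the median level 5 lay between -1.2 and -0.5, but Fndc3b at -0.44 did not. Among the dimmer genes Hltf, 4632415L05Rik and Pde7a lay in that range, at -0.97, -0.94 and -0.74, and the others did not. Ghsr, inside the run, had a wildtype mean of 7.79, just below the median level of 7.81. Its difference was -0.06, with a confidence interval of -0.26 to 0.14 that excludes -0.5. Sequence variants of another mouse strain under the probes could also lower the signal of 20 of 20 genes, and without values per single probe or genotypes these explanations cannot be told apart.

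Meningeal genes were higher in the transgenic group, but in 15 of the 17 genes the low values were those of wildtype replicates 2 and 3, below all other 4 arrays, as less meningeal tissue in those dissections would give. The most abundant, Ptgds, had 11.82 in wildtype replicate 1 and 10.52 and 10.33 in the other wildtype animals, 1 of the 17 genes is on another list, and 10 lay at or above the median level of all probes even in those 2 animals. Wildtype replicate 1 lay nearer to the transgenic mean than to the other wildtype animals by a median of 0.61, which goes against genotype but is 1 array and excludes nothing. Sex cannot be told apart from tissue makeup, because the same 2 animals carried the Y-linked signal, with a gap of 3.64 to the others, and only 1 wildtype array was without it. Genotype, sex and dissection therefore remain open.

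All 20 immediate early genes were higher in the transgenic group. The list's median was 0.33 with the Y-linked signal as a covariate and 0.27 without it. That fit rests on wildtype replicate 1, the lowest array for the list (-0.22, against -0.03 and -0.13 in wildtype replicates 2 and 3). The low values were thus not those of wildtype replicates 2 and 3 alone. Being 1 array, it cannot decide whether the makeup or sex that set those animals apart plays a part. Signal level or normalization is argued against as the whole cause, as 0 of 10000 level-matched lists had so high a median, the highest being 0.14. Handling or arousal may contribute, since the glucocorticoid list without genes of other lists still had a median of 0.11, with 8 of 10 genes above 0. The clock list without such genes had a median of 0.13, with 8 of 13 above 0. It mixes genes that peak at different times of day, so its median cannot decide whether time of day at death plays a part. The labels give neither handling, arousal nor time of death, so that they and genotype cannot be told apart.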
